A study of Homo sapiens with 7 samples.

How the data were processed

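Single-cell RNA sequencing libraries of 7 tumours, 3 UPS and 4 LMS from 6 patients, were analysed from the files that the submitters deposited. Per the labels' protocols, fresh tumours were minced and dissociated with enzymes and heating, and libraries were made with the 10x Genomics 3' kit, version 3.1, in which each transcript captured at its 3' end carries a UMI. Per the submitters' processing notes, the reads were processed with Cell Ranger 6.0.0 on GRCh38, while the file headers name Cell Ranger 4. The deposited matrices hold whole-number UMI counts, not normalized, for 36601 genes in every droplet barcode, per the file headers and the values. A separate deposited table, made by the authors, names a cell type for 15560 barcodes, and every one of them was found in the matrix of its tumour. How the authors chose and named these cells is not given in the sources used here. The series' design text says that the titles of 2 UPS samples were exchanged after the first deposit, which leaves the histology of both unchanged. The histology came from the labels, as did the fact that 2 LMS tumours share a patient.

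The matrices held 53707081 to 123245764 UMIs per tumour, of which 13125539 to 27884417 lay in annotated cells. Intervals and floors given with counts cover counting error only, at a confidence level of 95%, and a count of 0 is taken to allow 3 counts. Barcodes with at least 1000 UMIs and at most 15% mitochondrial counts that carry no annotation numbered 41278, and annotated cells were 21.4 to 33.2% of the barcodes passing these limits. The unannotated barcodes entered no gene or list test. They were used only in the later checks of compartment shares and of smooth muscle genes. Each was given the compartment (immune, malignant or stromal) of the annotated profile under which its counts were most likely, with profiles of at least 10 cells of the same tumour. In 5-fold cross-validation on annotated cells this gave the right compartment for 90.9 to 99.3% of the cells per tumour. The largest gap between annotated and unannotated shares of a compartment was 5.69 percentage points.

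Before any fit, 733 genes were removed: XIST, TSIX and Y-linked genes, segments of antibody and T cell receptor genes, and genes that some people lack, so that no sex or genotype is read. This left 35868 genes. Gene positions come from GENCODE release 29 on GRCh38, in which 34616 of the 36601 gene identifiers were found. Doublets were sought with Scrublet (scanpy 1.11.5, expected rate 0.06, per tumour), which marked 180 cells (1.16%). They stayed in the main results and were removed in an alternative. Free RNA was profiled in each tumour from droplets of 50 to 300 UMIs. Its upper share in each type was estimated from 7 collagen and matrix genes in immune types and 11 immune genes in the other types, on the assumption that these types express none of them.

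UMI counts were summed per patient within each annotated type, the patient being the replicate because cells of 1 tumour are not independent. A type was compared between the histologies where at least 2 patients each had 20 or more cells, which held for 7 of the 11 types. B cells, CD4 T cells, mast cells and malignant epithelial-like cells were left out of this test for want of cells. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr and robust dispersion, Benjamini-Hochberg adjusted within a type, with a threshold of 0.05. Folds are UPS over LMS. Mean CPM given with a fold or called scaled use TMM library sizes, and the CPM of single patients or tumours use plain totals. The naming rule took per type up to 10 genes in each direction with the largest fold among those past the threshold whose patients do not overlap, up to 4 members of each list with the smallest p, the 5 genes with the smallest p where none passed, and a fixed set of smooth muscle, collagen and growth genes in the malignant cells. Some genes that the rule took are not reported here. The genes named outside this rule, among them the single markers given for annotated types and the genes of the paired comparisons, were chosen after their values were seen.

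There were 28 functional gene lists and 19 lists of cell type markers. A list with 5 or more measured members was tested between the histologies with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the 176 list and type pairs. An estimated correlation and fry were the checks. For lists between types, the mean log2(CPM + 1) of a list in a type minus the mean over the other types of the patient was tested with an exact two-sided sign-flip permutation test over 6 patients (64 sign patterns, smallest p 0.0312). Shares of cells were tested with an exact two-sided permutation test of 3 against 3 patients (20 assignments, smallest p 0.1). No technical batch is given in the labels, so none was fitted.

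The edgeR step was tested on simulated counts with 200 changed genes per comparison, drawn from the means and library sizes of the real genes. At a log2 fold of 2 it recovered 78% of the changed genes in CD8 T cells, 62% in dendritic cells, 58% in endothelial cells, 28% in cancer-associated fibroblasts, 20% in monocytes and macrophages, 16% in malignant fibroblasts and 82% in NK cells, and at a log2 fold of 4 between 70% (malignant fibroblasts) and 100%. In simulated patients shifted by 1 SD, the sign-flip test reached its smallest p in 39% of the runs and the permutation test in 27.4%, and with a shift of 3 SD in 99.6% and 87.8%. With no shift they did so in 2.8% and 10%.

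The comparisons, the naming rule, the gene lists and the following alternatives were chosen before the data were examined: DESeq2 1.42.0, RLE factors, no filter on low counts, at least 50 cells per patient, 7 tumours as units, removal of Scrublet doublets, removal of genes for which free RNA could supply over 0.5 of the counts in either histology, leaving out each patient, an estimated correlation for lists, a pseudocount of 10 CPM, list medians, and shares within the immune or the other cells. The paired comparisons of malignant epithelial-like cells and of cancer-associated fibroblasts with malignant fibroblasts, fitted by edgeR with the patient as a block, and the compartments of unannotated barcodes were added after the data were seen. The pairing comes from the patients, since both types of a pair were measured in the same tumours. Other tools were Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.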

Results

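Dissociated cells of 7 tumours from 6 patients were profiled by droplet-based single-cell RNA sequencing. The tumours belong to 2 sarcoma histologies: undifferentiated pleomorphic sarcoma (UPS), which shows no recognisable line of differentiation, and leiomyosarcoma (LMS), a tumour with smooth muscle features. UPS 1, UPS 2 and UPS 3 came from patients UPS-A, UPS-B and UPS-C. LMS 1 came from patient LMS-A and LMS 2 from LMS-B, and LMS 3 and LMS 4 were both tumours of LMS-C. The authors' annotation named 15560 cells of 11 types, 7375 in UPS and 8185 in LMS, with 1236 cells in UPS 1, 2588 in UPS 2, 3551 in UPS 3, 2697 in LMS 1, 1903 in LMS 2, 1454 in LMS 3 and 2131 in LMS 4. The annotated cells held between 13125539 transcript counts (unique molecular identifiers, UMIs) in UPS 1 and 27884417 in UPS 2. The median per cell ran from 4558 UMIs in UPS 3 to 7923 in LMS 2. The patient was the replicate throughout, with 3 patients per histology and the counts of LMS 3 and LMS 4 summed.

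The first comparison asked whether the make-up of the tumours differed between the histologies. CD4 T cells, the helper lymphocytes, made up 4.75% ± 1.58 (SD, n = 3) of the annotated cells in UPS and 0.819% ± 1.16 (n = 3) in LMS, and the patients of the histologies did not overlap. B cells, the antibody lineage, made up 0.518% ± 0.555 in UPS and were named in 0 cells of LMS. The counts behind the B cells were small: 29 of 2588 cells in UPS 2 (1.12%, exact binomial 95% interval 0.752 to 1.61%), 5 in UPS 1 and 1 in UPS 3, against 0 of 2697, 1903, 1454 and 2131 cells in the LMS tumours, which allows shares of up to 0.111%, 0.158%, 0.206% and 0.141%. The exact binomial intervals of these LMS counts reach 0.137%, 0.194%, 0.253% and 0.173%. The 1 B cell of UPS 3 (0.0282%) lies below each of these bounds, so the separation of the histologies rests on that cell. Cancer-associated fibroblasts took 23.6% ± 19.0 of the cells in UPS and 5.45% ± 3.24 in LMS, a difference of 18.2 percentage points that ranged from 9.52 without UPS-C to 28.3 without UPS-A. Monocytes and macrophages took 9.39% in UPS and 25.8% in LMS, with 62.2% in LMS-A and 4.52% in LMS-B, and without LMS-A the difference turned to 1.78 percentage points more in UPS. Malignant fibroblasts, the authors' name for the main tumour cell population, took 20.3% and 39.8%, and the difference ranged from -37.0 points without LMS-A to -6.44 without LMS-C.

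None of the 11 types passed the exact two-sided permutation test, whose smallest possible p with 3 against 3 patients is 0.1. CD4 T cells and B cells reached it (exact p = 0.1 each, Benjamini-Hochberg adjusted p = 0.55 over the 11 types). For the other types the exact p lay between 0.3 and 0.9. As shares of the immune cells alone, monocytes and macrophages differed by -43.6 percentage points and dendritic cells by 14.9, and both reached the smallest p as well (exact p = 0.1 each, adjusted p = 0.275). The cells named dendritic carried macrophage markers at a mean log2 level of 9.94, beside 9.22 in those named monocytes and macrophages. Whether the opposite shifts reflect how these cells were named was not tested. With immune types summed, the share was 30.7% ± 11.4 in UPS and 34.9% ± 40.1 in LMS (exact p = 1), and with both malignant types summed it was 24.9% ± 21.4 and 47.1% ± 34.3 (exact p = 0.4). Among the LMS patients, immune cells were 80.6% of the cells in LMS-A, 5.68% in LMS-B and 18.4% in LMS-C.

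**Figure D1:**
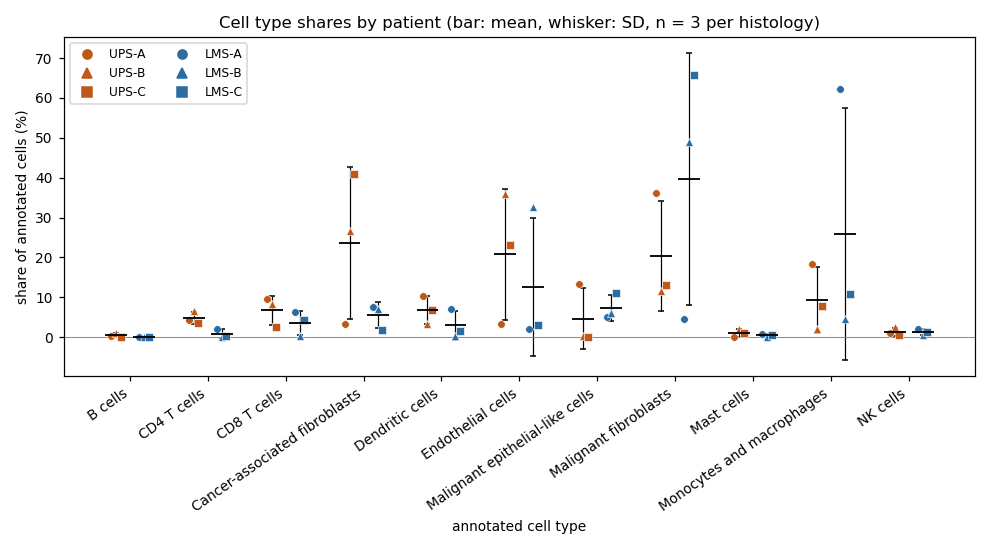
Share of annotated cells (percent, vertical axis) for each of the 11 annotated types, with 1 point per patient and the mean and SD (n = 3) of UPS and LMS. The shares of CD4 T cells in UPS (3.52 to 6.53%) lie above those in LMS (0 to 2.15%).

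The next comparison placed 28 functional gene lists in the 4 types that had 20 or more cells in all 6 patients: cancer-associated fibroblasts, endothelial cells, malignant fibroblasts, and monocytes and macrophages. Genes of antigen presentation on MHC class II, the molecules that show peptides to helper T cells, were highest in monocytes and macrophages, by 3.83 ± 0.61 on the log2 scale over the other types of the same patient (SD, n = 6, higher in 6 of 6 patients). They were lowest in malignant fibroblasts, at -3.58 ± 0.79. Malignant fibroblasts also had lower levels of MHC class I genes, which present peptides to cytotoxic T cells (-1.27 ± 0.49), of interferon gamma response genes (-1.42 ± 0.44) and of type I interferon response genes (-1.47 ± 0.86), in 6 of 6 patients each. Dissociation stress genes (-0.90 ± 0.82) and the complement and resident-type macrophage list (-2.59 ± 0.97) were lower in these cells too, in 6 of 6 patients. Checkpoint ligands, which inhibit T cells, were higher in monocytes and macrophages by 0.91 ± 0.28, as were the complement and resident-type macrophage list (3.98 ± 0.65) and the inflammatory monocyte list (2.68 ± 0.78).

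Endothelial cells, which line blood vessels, were higher in the angiogenic (3.03 ± 0.98), adhesion (2.90 ± 1.05) and basement membrane (1.67 ± 0.88) lists and in MHC class I genes (0.88 ± 0.30). Fibrillar collagen and matrix genes were higher in cancer-associated fibroblasts by 2.14 ± 1.34 and in malignant fibroblasts by 1.83 ± 0.85. Smooth muscle contractile genes were higher in cancer-associated fibroblasts by 2.32 ± 0.96 over the mean of the other types. Malignant fibroblasts lay higher still in LMS-B (2.18 against 0.63) and LMS-C (3.30 against 2.14), and below cancer-associated fibroblasts in the other patients. Genes of the G2/M phase of the cell cycle were lower in cancer-associated fibroblasts, at -1.40 ± 0.82. Of the 112 list and type pairs, 38 had the same sign in all 6 patients and so reached the smallest p that the exact two-sided sign-flip permutation test can give with 6 patients, 0.0312. None passed after adjustment over the 112 pairs (smallest adjusted p = 0.0921), so these are differences that held in each patient without passing the corrected test. Macrophage and endothelial lists were high in cells that may have been named by such genes, so their placement is a description only.

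**Figure D2:**
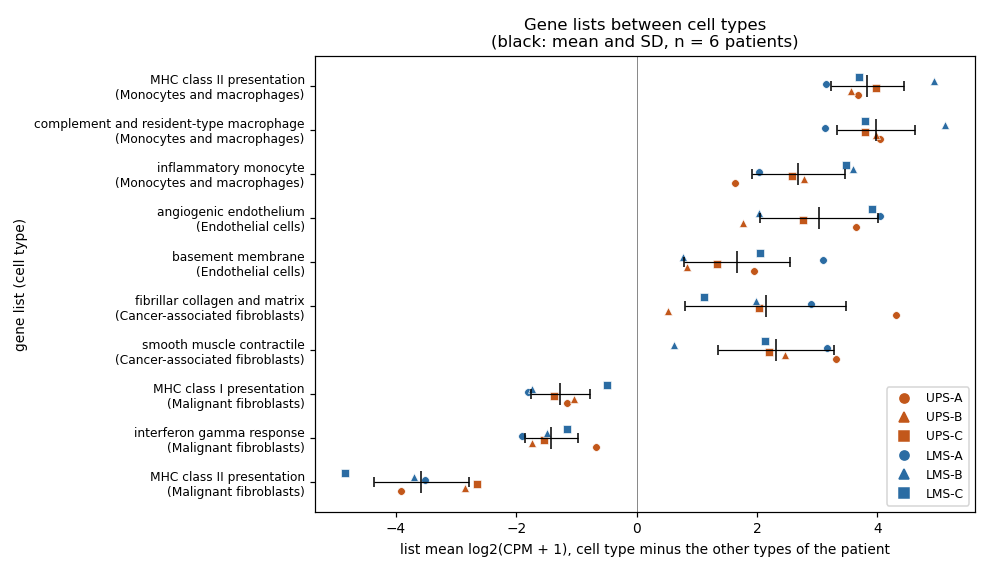
Mean log2(CPM + 1) of a gene list in 1 cell type minus its mean over the other types of the same patient (horizontal axis, log2 units), with 1 point per patient and the mean and SD of 6 patients in black. The points of each list shown lie on 1 side of 0, from the macrophage lists at 3.98 to MHC class II in malignant fibroblasts at -3.58. Macrophage and endothelial lists lie high in cells that may have been named by such genes.

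Between the histologies, malignant fibroblasts of LMS carried the smooth muscle programme in 2 of the 3 patients. Desmin (DES, the intermediate filament of muscle, chr2:219418377-219426739 in GRCh38) stood at 1088 CPM (its counts scaled to a fixed library total) in LMS-B and 963 in LMS-C, at 0 in LMS-A, and at 0, 0 and 0.225 in UPS-A, UPS-B and UPS-C. The 0 of LMS-A came from 125 cells and allows up to 1.19 CPM. Smooth muscle actin (ACTA2, chr10:88935074-88991339) stood at 5858 and 3790 CPM in LMS-B and LMS-C, at 28.6 in LMS-A and at 36.5 to 109 in UPS. The smooth muscle myosin MYH11 stood at 2139, 3431 and 0.795 CPM in LMS-B, LMS-C and LMS-A, and the actin-binding proteins CNN1 at 948, 1149 and 11.9 and TAGLN at 7842, 6415 and 89.8. Of 20 measured smooth muscle contractile genes, 0 passed over all genes and 13 passed adjusted over the list alone, all with lower values in UPS (median log2 difference -4.25; adjusted p = 0.663 with an estimated correlation).

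Fibrillar collagen and matrix genes went the other way. All 22 measured members were higher in malignant fibroblasts of UPS, with a median log2 difference of 2.50; 9 passed adjusted over the list alone and 0 over all genes (adjusted p = 0.538 with an estimated correlation). Type I collagen (COL1A1, chr17:50183289-50201632) averaged 8143 ± 5678 scaled CPM in UPS and 580 ± 122 in LMS (log2 difference 3.81 ± 0.67 SE, edgeR adjusted p = 0.272), and the matrix proteoglycan DCN differed by 6.91 ± 0.98 (adjusted p = 0.208, edgeR). All 20 type I interferon response genes were higher in UPS (median 1.26), of which 1 passed adjusted over the list alone (adjusted p = 0.758 with an estimated correlation). Examples were IFI27, at 2.82 ± 0.60, and OAS1, at 2.05 ± 0.95. The proliferation marker MKI67 differed by 0.45 ± 1.53 and the cell cycle and p53 regulators CDK4 and MDM2, both on chromosome 12, by 0.10 ± 0.45 and -0.46 ± 0.46, each within its error. The signs of CDK4 and MKI67 turned without LMS-C or without UPS-B.

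No gene of 12846 passed in malignant fibroblasts by edgeR's quasi-likelihood test (n = 3 against 3 patients), with 954 genes at an unadjusted p under 0.05 and 235 passing by DESeq2. DES was not among the 12846 genes. The filter on low counts asks for 3 patients in this fit, and only LMS-B and LMS-C had enough DES counts. DES entered the fit without LMS-A, where the smaller group has 2 patients, so its pass there is not a change from a failed test. The smallest p belonged to BCHE, a cholinesterase, at 0.171 against 94.7 CPM (3 UMIs in UPS; ratio of summed counts 466, exact 95% counting interval 159 to 2259; edgeR adjusted p = 0.0592). It was followed by the adhesion receptor ADGRG2, higher in UPS at 42.1 ± 34.5 against 0.251 ± 0.117 CPM (adjusted p = 0.0593, edgeR). Then came ZNF728 (2 UMIs in UPS, ratio 96.0, interval 26.4 to 795), the calcium-binding protein S100A4 (4086 ± 453 against 265 ± 116, adjusted p = 0.208) and the ganglioside synthase ST3GAL5 (26.1 against 0.782). Patients did not overlap between the histologies for 1668 genes (13%; chance gives 10%). Without LMS-A, 14 genes passed, among them DES, MYH11 and CNN1 (edgeR adjusted p = 0.0162 each; over the alternatives of these genes the adjusted p ran from 1.35e-09 by DESeq2 to 0.885), and without UPS-B 1 gene passed.

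**Figure D3:**
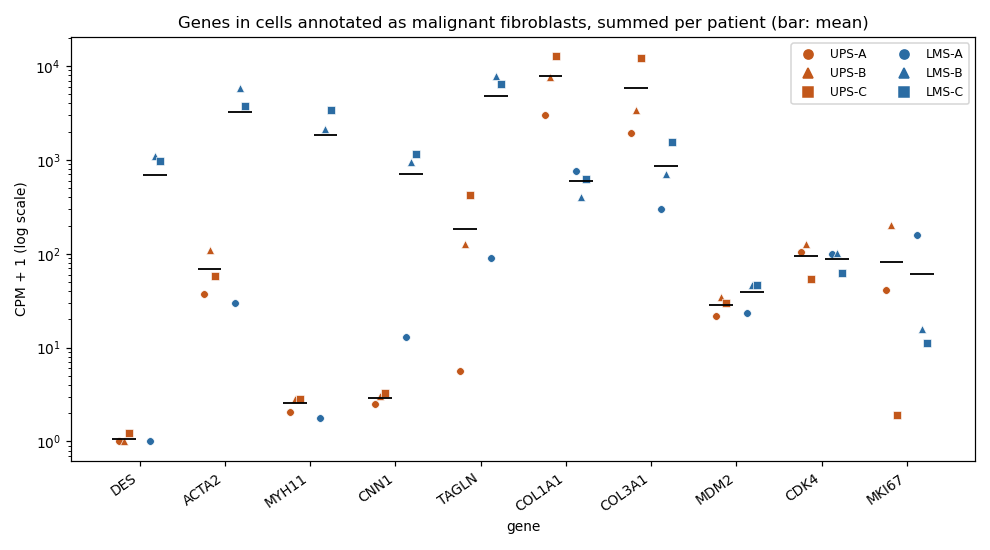
CPM plus 1 (log scale, vertical axis) of smooth muscle, collagen and growth genes in the malignant fibroblasts of each patient, with 1 point per patient and the mean of UPS and of LMS as a bar. For DES, MYH11, CNN1, ACTA2 and TAGLN, LMS-B and LMS-C lie above every UPS patient and above LMS-A.

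CD8 T cells, the cytotoxic lymphocytes, gave 24 of the 27 genes that passed between the histologies over the 7 tested types. In them 24 of 4313 genes fell in UPS relative to LMS and 0 rose (edgeR, n = 3 UPS against 2 LMS patients; LMS-B had 7 such cells and stayed out). HSP90AA1 (the molecular chaperone Hsp90, chr14:102080738-102139699) averaged 1977 ± 1144 scaled CPM in UPS and 14560 ± 953 in LMS (log2 difference -2.88 ± 0.44 SE, edgeR adjusted p = 0.0312). The mitochondrial chaperonin HSPD1 (chr2:197486581-197516737) averaged 272 ± 55.8 and 2072 ± 101 (-2.93 ± 0.28, adjusted p = 0.00415, edgeR), and HSPH1 225 ± 68.6 and 1958 ± 453 (-3.12 ± 0.34, adjusted p = 0.00654, edgeR). HSPA6 (chr1:161524540-161526910), an Hsp70 that is nearly silent without stress and has a near-identical copy, HSPA7, had 1 UMI in UPS and 435 in LMS, a ratio of 382 (exact 95% counting interval 68.3 to 15141).

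Other genes that the naming rule took were DNAJB4, BAG3, FKBP4 and CACYBP, which work with Hsp70 and Hsp90, and the stress-induced ZFAND2A, with log2 differences from -3.71 to -2.95. Of the 18 measured dissociation stress genes, a list that mixes heat-shock and immediate early genes, HSP90AA1 and DNAJB1 fell, and 6 passed adjusted over the list alone (median -0.85, adjusted p = 0.538 with an estimated correlation). The immediate early genes FOS (0.27 ± 0.55) and EGR1 (0.28 ± 0.64), chosen after their values were seen, did not pass, and neither did HSPA1A (205 ± 182 against 5311 ± 2022, adjusted p = 0.0529, edgeR), whose reads a near-identical copy shares. Summed over the 24 genes, the CD8 T cells held 4617, 4534 and 7316 CPM in UPS-A, UPS-B and UPS-C against 37479 in LMS-A and 27661 in LMS-C. The 7 CD8 T cells of LMS-B held 84 UMIs of these genes among 21663, or 3878 CPM (exact Poisson 95% interval 3093 to 4801), a level below LMS-A and LMS-C.

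The same 24 genes, chosen in CD8 T cells, were lower in UPS than in LMS-A and LMS-C in other types too. The median log2 difference was -2.31 in NK cells, -1.76 in dendritic cells, -1.51 in cancer-associated fibroblasts, -0.89 in monocytes and macrophages, -0.88 in endothelial cells and -0.62 in malignant fibroblasts. The 11 measured collagen and matrix genes had a median difference of 2.37 in CD8 T cells, with 0 passing over all genes and 5 adjusted over the list alone (adjusted p = 0.538 with an estimated correlation). Free RNA could supply up to 17.5% of all counts of these cells in UPS 3 and up to 6.82% in the tested LMS tumours. These are not shares of the collagen counts. In UPS 3, UMIs of 13 collagen genes not used for the estimate were 1.08 times those expected from free RNA, a ratio that fibroblasts would give too. Of 14 cytotoxicity genes, 11 were higher in UPS (median 0.54; 0 passing over all genes and 0 adjusted over the list alone; adjusted p = 0.758 with an estimated correlation). Examples were the granzyme GZMK at 1.61 ± 0.44 and the receptor KLRK1 at 1.30 ± 0.38, while the cytokine IFNG stood at -1.07 ± 0.38. With LMS-A or LMS-C left out, LMS has 1 patient that is taken to vary like the others. HSPA6 passed in each fit without 1 patient (largest edgeR adjusted p = 0.0157), HSPD1 and HSPH1 did not pass without UPS-B (0.0835 each), and HSP90AA1 did not without LMS-A, LMS-C, UPS-A or UPS-B (0.0583, 0.0727, 0.114 and 0.209). The count of 24 fell to 1 without UPS-B and to 5 without UPS-A, and was 37 by DESeq2 (5 higher, 32 lower), 46 with no filter on low counts (3 higher, 43 lower) and 41 with 7 tumours as units (6 higher, 35 lower).

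**Figure D4:**
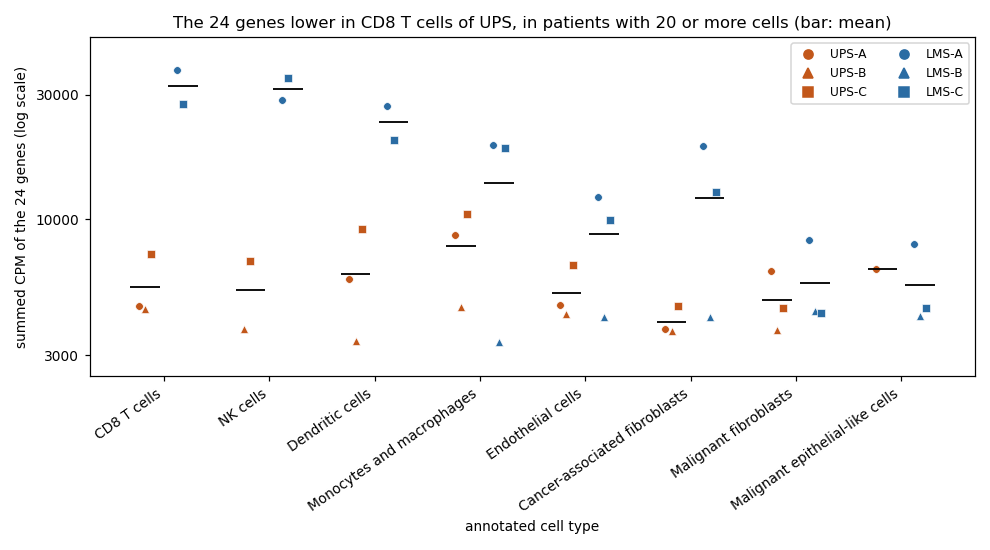
Summed CPM (log scale, vertical axis) of the 24 genes lower in CD8 T cells of UPS, in each cell type and patient with 20 or more cells, with 1 point per patient and the mean of UPS and of LMS as a bar. LMS-A and LMS-C lie above the UPS patients in the non-malignant types, and LMS-B, where measured, lies near or below the UPS patients.

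In dendritic cells 3 of 7117 genes rose in UPS and 0 fell (edgeR, n = 3 UPS against 2 LMS patients, without LMS-B). The growth factor IGF1 (chr12:102395874-102481744) averaged 124 ± 27.4 scaled CPM in UPS and 1.53 ± 0.626 in LMS, and since LMS held 2 UMIs its ratio of 90.3 has an exact 95% counting interval of 24.9 to 748 (edgeR adjusted p = 0.00376). The iron exporter SLC40A1 (chr2:189560579-189583758) averaged 332 ± 68.5 and 7.22 ± 0.963 (log2 difference 5.52 ± 0.44, adjusted p = 0.00855, edgeR). The third was AC253572.2, a transcript outside the naming rule that was chosen after its values were seen (adjusted p = 0.0415, edgeR). Of 18 complement and resident-type macrophage genes, 17 were higher in UPS (median 1.57), 1 passed over all genes and 4 adjusted over the list alone (adjusted p = 0.647 with an estimated correlation), with SELENOP at 5.47 ± 0.80 and FOLR2 at 3.74 ± 0.67 as examples. Macrophage markers moved with it, higher in 7 of 8 (median 0.76; adjusted p = 0.758 with an estimated correlation). MHC class II genes were higher in 11 of 12 (median 1.58, 0 passing over all genes, 9 adjusted over the list alone; adjusted p = 0.604 with an estimated correlation). Inflammatory monocyte genes had a median of -1.06 over 16 members, with 0 passing over all genes and 7 adjusted over the list alone (adjusted p = 0.538 with an estimated correlation). They split: the alarmins S100A8 (-4.06 ± 0.50) and S100A12 (-3.81 ± 0.45) were lower and the cytokine TNF (3.06 ± 0.53) higher in UPS.

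The cells named dendritic expressed macrophage markers at a mean of 9.94 ± 0.41 (log2(CPM + 1), SD over patients) and dendritic markers at 2.72 ± 1.70. The macrophage complement gene C1QA stood between 571 and 8984 CPM in them, and CD1C, a dendritic marker, had 0 UMIs in LMS 1 and LMS 4. Collagen and matrix genes were higher in UPS here too (median 2.09 over 14 genes, 0 passing over all genes, 8 adjusted over the list alone; adjusted p = 0.748 with an estimated correlation). No gene passed without LMS-A or without LMS-C, fits with 1 LMS patient (IGF1 and SLC40A1 both at an edgeR adjusted p of 0.101 and 0.135; from 2.14e-15 to 0.135 over their alternatives), and 7 passed without UPS-C. DESeq2 called 145 genes (81 higher, 64 lower), the test with no filter 88 (42 higher, 46 lower), and 1 was left when genes that free RNA could supply were removed.

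In endothelial cells all 20 measured G2/M phase genes had higher mean values in UPS (median 2.52), with 17 passing adjusted over the list alone and 0 over all genes (adjusted p = 0.538 with an estimated correlation). The mitotic kinases BUB1 and AURKB were higher by 3.35 ± 0.74 and 3.32 ± 0.75, and BIRC5 and TPX2 by 3.07 ± 0.71 and 2.65 ± 0.65. All 19 S phase genes were higher too, at a median of 0.65, with 0 passing either way (adjusted p = 0.538 with an estimated correlation), as were 15 of 15 interferon gamma response genes at a median of 0.83 (0 passing either way; adjusted p = 0.718 with an estimated correlation). Fibroblast and pericyte markers moved with these lists, at medians of 2.43 and 2.07, and collagen genes at 1.48. So did T cell markers, higher in 6 of 7 (median 1.44; adjusted p = 0.819 with an estimated correlation), and cytotoxicity genes, in 9 of 11 (1.32; adjusted p = 0.816 with an estimated correlation). By edgeR 0 of 12498 genes passed (n = 3 against 3 patients), with 478 at an unadjusted p under 0.05 and 37 passing by DESeq2. The smallest p were those of TFF3 (2.45 ± 0.598 against 33.8 ± 14.2 CPM) and MXRA8 (16.5 ± 1.50 against 1.96 ± 0.856), at an edgeR adjusted p of 0.0897 each. Next came KIF23 (2 UMIs in LMS, ratio 36.3, exact 95% counting interval 9.92 to 302), DPP4 and CMBL.

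Cancer-associated fibroblasts of UPS had higher collagen genes in 23 of 23 measured members (median 2.36, 0 passing over all genes and 0 adjusted over the list alone; adjusted p = 0.538 with an estimated correlation). COL1A1 differed by 3.50 ± 0.89 and COL1A2 by 2.56 ± 0.71. All 10 MHC class II genes were lower in UPS (median -2.93, 0 passing either way; adjusted p = 0.663 with an estimated correlation), with CD74, the class II invariant chain, at -2.93 ± 0.98. Macrophage markers moved with them, at a median of -3.21, and the cells of this name carried C1QA at 2028 CPM in LMS 1 and 1424 in LMS 4 against 7.26 in UPS 2 and 50.7 in UPS 3, while LMS 2 stood at 2.27 (3 UMIs) and UPS 1 at 766. By the estimate from immune genes, the free RNA share of this type reached its cap of 100% in LMS 3 and LMS 4. Immune genes there made up at least as large a part of the counts as in free RNA itself. The estimate assumes that these cells express none of them, so the value gives no usable bound. Immune cells under this name stay possible. By edgeR 0 of 9912 genes passed (n = 3 against 3), with 408 at an unadjusted p under 0.05, 26 passing by DESeq2 and 2 without LMS-B. GIMAP5 (-3.05 ± 0.43) and the growth factor HBEGF (-2.74 ± 0.35) had the smallest p (edgeR adjusted p = 0.504 each), followed by SAT1, RNF144B and CCRL2.

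Monocytes and macrophages of UPS had lower inflammatory monocyte genes, with 12 of 15 below LMS (median -1.42, 0 passing over all genes and 0 adjusted over the list alone; adjusted p = 0.538 with an estimated correlation). Examples were the inflammasome sensor NLRP3 (-1.38 ± 0.48), the prostaglandin synthase PTGS2 (-1.62 ± 0.50) and the chemokine CCL4 (-1.88 ± 0.71). Other myeloid lists were lower too: macrophage markers in 6 of 8 members (median -0.79, adjusted p = 0.816 with an estimated correlation), MHC class II in 12 of 12 (-0.78, adjusted p = 0.78 with an estimated correlation) and the complement and resident-type list in 12 of 18 (-0.33, adjusted p = 0.84 with an estimated correlation). The SPP1 and lipid-handling macrophage list was not, with 7 of 13 members higher in UPS (median 0.25, adjusted p = 0.895 with an estimated correlation). Interferon gamma response genes were higher in 13 of 14 (median 1.05; 0 passing either way; adjusted p = 0.762 with an estimated correlation). Collagen genes were higher in 16 of 17 (median 2.91, 2 passing adjusted over the list alone; adjusted p = 0.663 with an estimated correlation), led by DCN at 235 ± 273 against 3.03 ± 2.63 CPM, and endothelial markers had a median of 2.30 (adjusted p = 0.762 with an estimated correlation). Smooth muscle markers were lower in 6 of 6 (median -3.63; adjusted p = 0.758 with an estimated correlation). Free RNA could supply up to 50.5% of the counts of these cells in UPS 3, 28.1% in LMS 2 and 9.31% in UPS 2, against 1.45 to 3.76% in the other tumours. By edgeR 0 of 8805 genes passed (n = 3 against 3), with 247 at an unadjusted p under 0.05 and 6 passing by DESeq2. PLAC9, DCN, PCOLCE, GPR82 and IL1RAP had the smallest p.

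NK cells, the innate cytotoxic lymphocytes, had 20 or more cells in 2 patients of each histology. By edgeR 0 of 2192 genes passed, with 160 at an unadjusted p under 0.05 and 20 passing by DESeq2. The test called 98 genes without LMS-A, 66 without LMS-C and 34 without UPS-B, fits in which a histology has 1 patient that is taken to vary like the others. The smallest p belonged to HSPA6, with 0 UMIs in UPS and at least 36.4-fold higher in LMS against a floor of 3 counts over the histology (the exact two-sided 95% interval of the ratio starts at 29.2). Next were CACYBP (55.0 ± 40.7 against 853 ± 4.75 CPM), HSP90AB1 (850 ± 204 against 5197 ± 1392), and the matrix genes MGP (3 UMIs in LMS, ratio 18.1, exact 95% counting interval 5.81 to 91.3) and SPARC (422 ± 106 against 28.8 ± 13.1), all at an edgeR adjusted p of 0.0608. Dissociation stress genes had a median of -1.02 over 18 members, with 0 passing over all genes and 7 adjusted over the list alone (adjusted p = 0.538 with an estimated correlation). T cell markers were higher in UPS (median 1.43), and the T cell receptor component CD3D stood at 840 CPM in the NK cells of UPS 2, 149 in UPS 3, 41.8 in LMS 1 and 39.3 in LMS 4.

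Over the 7 types, 176 list and type pairs were tested, and 58 passed with camera's preset correlation, 36 higher and 22 lower in UPS. With an estimated correlation 0 passed (smallest adjusted p = 0.512), and by fry 0 passed (smallest adjusted p = 0.566). In the 4 types with 3 patients per histology the real grouping gave 42 preset calls and the 9 other groupings of the patients 30 to 58, so the preset calls are a description of which genes moved together in these patients.

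The last comparison set LMS 3 and LMS 4, the tumours of 1 patient, beside each other, with values only because there is 1 such patient. Their malignant fibroblasts had a correlation of 0.995 across 14227 genes (log2 CPM; genes are not independent replicates), against 0.71 to 0.83 for tumours of different LMS patients. Between them 0% of the genes differed over 4-fold, against 3.53 to 6.83%. In malignant epithelial-like cells the correlation was 0.979 (0.647 to 0.781 between patients), in monocytes and macrophages 0.984 (0.725 to 0.945), in CD8 T cells 0.954 (0.877) and in endothelial cells 0.949 (0.848 to 0.955), where it was not above that of every pair of patients. Smooth muscle contractile genes of the malignant fibroblasts differed by -0.04 on the log2 scale (LMS 4 minus LMS 3). Of the lists and types compared, cytotoxicity genes in malignant epithelial-like cells differed most, by 2.48 from a level of 0.27 in LMS 3. Genes of naive and memory T cells (1.07) and of T cell exhaustion (0.89) moved with them in these cells. Other wide differences were SPP1 and lipid-handling macrophage genes by -1.27 in monocytes and macrophages, and in endothelial cells G2/M phase genes by 1.34 and angiogenic genes by -1.20. Immune cells made up 18.7% of the cells in LMS 3 and 18.2% in LMS 4, and malignant cells 78.2% and 76.1%.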

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

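The tests of the CD8 T cell and smooth muscle patterns below, and the assignment of unannotated barcodes, were chosen after the results were seen. Among the 4 LMS tumours 26 quantities were looked at for a single tumour far from the rest, and 5 stood out. Chance gives about 1 in 20 for independent tumours, a rate that does not hold here because LMS 3 and LMS 4 come from 1 patient. LMS 2 had 32.6% endothelial cells against 2.08 to 3.43% in the other LMS tumours. LMS 1 had 62.2% monocytes and macrophages against 4.52 to 11.8%. In malignant fibroblasts LMS 1 also had 22.6 CPM of MDM2 against 45.1 to 46.2, and 157 CPM of MKI67 against 8.63 to 14.7. HSPA1A in monocytes and macrophages stood at 161 CPM in LMS 2 against 5470 to 6313. Of 112 list and type pairs, 1 had all 3 UPS patients on one side of 0 and all 3 LMS patients on the other. The G2/M phase genes of endothelial cells lay above the other types of the same patient by 1.49 (log2) in UPS and at -0.69 in LMS, a difference of 2.18. Its exact permutation p was 0.1, the smallest that 3 against 3 patients can give, so the difference is not shown.

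The matrices also held 41278 barcodes without annotation that had 1000 or more UMIs and at most 15% mitochondrial counts. With each assigned to its nearest profile, all barcodes together gave immune shares of 29.4% ± 9.63 (SD, n = 3 patients) in UPS and 33% ± 42.1 in LMS (exact permutation p = 1). Malignant shares were 27.3% ± 22.9 and 48.8% ± 35.8 (exact p = 0.5), and stromal shares 43.3% ± 32.3 and 18% ± 19.4 (exact p = 0.3).

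The 24 genes lower in CD8 T cells of UPS, HSP90AA1 and HSPA6 among them, were weighed against 3 explanations. Free RNA is argued against as the whole cause, since it could supply a share of at most 0.0757 of the UMIs of any of these genes in LMS CD8 T cells. A stress shared by the other cells of each tumour stays open: in 3 of 5 other non-malignant types the median log2 ratio of UPS to LMS-A and LMS-C was at or under -1, with 22 to 24 of 24 genes lower in each of the 5, and in malignant fibroblasts it was -0.62, with 20 of 24 genes lower. In malignant fibroblasts the summed CPM of LMS-C (4340) lay under those of UPS-A (6306) and UPS-C (4554), and that of LMS-A (8306) above them. The malignant cells of LMS-C thus did not share a high summed level. The 7 CD8 T cells of LMS-B stood at 3878 CPM (exact Poisson interval 3093 to 4801). This lies below the 27661 or more of LMS-A and LMS-C by more than counting error. The high level was therefore not seen in every LMS patient. Histology stays open too as a cause, because the low level rests on 7 cells of 1 patient. In LMS-B the medians against LMS-A and LMS-C were -1.52 in monocytes and macrophages, -1.36 in cancer-associated fibroblasts, -1.11 in endothelial cells and -0.73 in malignant fibroblasts.

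The near absence of smooth muscle genes from malignant fibroblasts of LMS-A was weighed against 3 technical explanations. Depth is argued against, since 2425 UMIs of DES would be expected at the lower level of the other LMS patients and 0 were seen. A large group of smooth muscle-like cells left out of the annotation is argued against by a summed 9.31 CPM of DES, MYH11 and CNN1 in the unannotated barcodes of LMS-A, beside 2642 in LMS-B, 4395 in LMS-C and 12.1 to 45.8 in UPS. These CPM pool all unannotated barcodes of a patient. Of them 9.47% were assigned to malignant cells in LMS-A, 57.7% in LMS-B, and 80.2 and 80.8% in LMS 3 and LMS 4. A small group would be diluted in this sum and stays possible. A swap between the histologies is argued against by 0 UPS patients with DES at or over 0.1 times the lower LMS level, while a single wrong label or a wrong naming of the cells stays open. No biological explanation was tested, since no group in the labels separates LMS-A from the other LMS patients.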

How the results depend on the processing

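The alternatives of the 2 paired comparisons were chosen after the data were seen. Of the 46 named genes, 453 results under alternatives kept direction and side of the threshold, 60 newly passed, 27 no longer passed and 4 turned sign; of the shares, 95 kept their direction and 4 turned. The shares that turned were monocytes and macrophages, at 1.78 percentage points without LMS-A (-27.1 without LMS-B), and NK cells, at -0.647 within the immune cells and from -0.426 (without UPS-B) to 0.535 (without LMS-A), with -0.256 without LMS-B. CDK4 in malignant fibroblasts turned to -0.15 without LMS-C and -0.08 without UPS-B (highest 0.36), and MKI67 to -0.06 and -1.40 (highest 2.56, log2). The 27 genes that passed between the histologies became 506 by DESeq2, 178 with no filter on low counts and 57 with 7 tumours as units. Leaving out 1 patient gave from 2 genes (without LMS-B, in the 4 types it could be left out of, where the full count is 0) to 145 (without LMS-A), with 7 without UPS-A and 85 without LMS-C. RLE factors, at least 50 cells, removal of doublets and removal of genes that free RNA could supply gave 27, 27, 28 and 27. The last count differs by type from the main one: 25 in CD8 T cells in place of 24, 1 in dendritic cells in place of 3, and 1 in endothelial cells in place of 0. The 58 list calls became 0 with an estimated correlation. Without LMS-B they were 47, from 126 list and type pairs in place of 176. This is not a fall, since the same 4 types gave 42 calls in the main run. With any other patient left out the calls ran from 49 (without UPS-B, 183 pairs) to 91 (without LMS-A, 196 pairs). The lists between types had 0 adjusted passes under a pseudocount of 10, list medians and no doublets, with 37, 33 and 39 pairs at the smallest p. With 7 tumours as units the shares of CD4 T cells and B cells reached an exact permutation p of 0.0571, the smallest for 3 against 4, and an adjusted p of 0.314.

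For malignant fibroblasts against cancer-associated fibroblasts the count of 0 became 51 with no filter and 731 by DESeq2, and ranged from 0 to 39 (without UPS-C) with 1 patient left out, at 2 without LMS-B and 1 each without LMS-C and UPS-A. For malignant epithelial-like cells against malignant fibroblasts the 1099 genes became 0 without the patient as a block, and 97 (without UPS-A), 434 (without LMS-C), 693 (without LMS-A) and 739 (without LMS-B). The causes were not tested, except that fewer patients give fewer degrees of freedom. Without the block, the other paired count stayed at 0. No paired analysis was possible between UPS and LMS because no patient has both. No alternative scaling moved the median log2 difference of all genes by over 0.1. Depth and cell number limit what could be tested: 4313 genes passed the filter in CD8 T cells and 2192 in NK cells against 12846 in malignant fibroblasts.

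Other divisions of the 6 patients into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real division called 0 genes in cancer-associated fibroblasts, endothelial cells, malignant fibroblasts and monocytes and macrophages, which any division equals (10 of 10), so the comparison tells nothing about chance. The highest other counts were 0, 0, 1 and 485. The division with 485, LMS-A, LMS-C and UPS-A against LMS-B, UPS-B and UPS-C, points to a structure of the samples. The upper free RNA shares of these cells were 2.53%, 2.70% and 3.76% at most in the first 3 patients and 28.1%, 9.31% and 50.5% in the others, and whether they lie behind the calls was not tested. For lists the real division gave 42 calls and 9 of 10 gave as many, up to 58. With the types exchanged within patients, the same holds for malignant fibroblasts against cancer-associated fibroblasts (real 0, highest other 1, 32 of 32 as large), where the count of 0 fixes the outcome. The 8 divisions of malignant epithelial-like cells are too few (1 as large; real 1099, highest other 0).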

Other observations

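The 2 comparisons of tumour cell types and the tests of collagen genes in immune cells were chosen after the data were seen, apart from the test of fibroblasts and doublets among immune cells. Both comparisons of cell types set apart cells that the authors may have named by the expression of such genes. Fibroblast markers, for example, fell in 4 of 7 measured members in malignant epithelial-like cells against malignant fibroblasts. The p-values of these comparisons therefore describe the named types and are not independent evidence that the types differ. Malignant epithelial-like cells, the authors' second malignant type, differed from malignant fibroblasts of the same patients in proliferation, antigen presentation and matrix (LMS-A, LMS-B, LMS-C and UPS-A; 814 against 3862 cells). By edgeR with the patient as a block 416 of 11764 genes rose and 683 fell (544 and 466 with RLE factors). Without the block 0 passed, with 97 passing without UPS-A, 434 without LMS-C and 693 without LMS-A. S phase genes rose in 7 of 20 measured members, 15 adjusted over the list alone (adjusted p = 0.298 with an estimated correlation). Examples were thymidylate synthase TYMS (2.05 ± 0.31 SE on the log2 scale, edgeR adjusted p = 0.0176) and thymidine kinase TK1 (2.36 ± 0.42, edgeR adjusted p = 0.0312). G2/M genes rose in 5 of 20 (9 over the list alone; adjusted p = 0.298 with an estimated correlation). Type I interferon response genes rose in 9 of 20 (adjusted p = 0.256 with an estimated correlation), with ISG15 at 1.16 ± 0.13 (edgeR adjusted p = 0.00147). MHC class I genes rose in 6 of 12 and class II in 6 of 10 (adjusted p = 0.293 each with an estimated correlation), with HLA-B at 0.77 ± 0.16 and HLA-DRA at 1.27 ± 0.24 (edgeR adjusted p = 0.0231 each). Collagen and matrix genes fell in 15 of 22 (adjusted p = 0.196 with an estimated correlation), with COL1A1 at -1.11 ± 0.11 (edgeR adjusted p = 8.44e-04) and COL3A1 at -1.41 ± 0.12 (edgeR adjusted p = 2.60e-04). Basement membrane genes fell in 9 of 12 (adjusted p = 0.256 with an estimated correlation) and smooth muscle genes in 9 of 23 (adjusted p = 0.298 with an estimated correlation), with MYH11 at -0.95 ± 0.17 (edgeR adjusted p = 0.0081). Macrophage markers moved with the class II genes, at a median of 0.81 against 1.09, and rose in 1 of 8 members (adjusted p = 0.462 with an estimated correlation). The upper free RNA share, set on immune genes, was higher in malignant epithelial-like cells than in malignant fibroblasts of each tumour. It was 16.3 against 5.34% in LMS 1, 5.58 against 5.48% in LMS 2 and 2.18 against 1.81% in LMS 3. In LMS 4 it was 3.40 against 2.28%, and in UPS 1 3.53 against 2.95%. With genes removed for which free RNA could supply over 0.5 of the counts in either type, 427 of 11658 genes rose and 696 fell. This count does not single out the antigen presentation genes, so whether free RNA lies behind their rise stays open. Epithelial markers averaged 1.44 ± 0.76 (log2(CPM + 1), SD) in the malignant epithelial-like cells of these 4 patients and 1.12 ± 0.59 in malignant fibroblasts of all 6, and the keratin KRT18 differed by 0.30 (edgeR adjusted p = 0.394).

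Against cancer-associated fibroblasts of the same 6 patients, malignant fibroblasts had higher G2/M genes (median log2 difference 2.58, 14 of 19 passing adjusted over the list alone, adjusted p = 0.289 with an estimated correlation). UPS-C went the other way. Set against the other types of that patient, its G2/M list stood at -2.41 in malignant fibroblasts and -1.33 in cancer-associated fibroblasts. Malignant fibroblasts had lower pericyte markers (-3.53, 6 of 8 passing over the list alone), MHC class II (-2.33, 10 of 10), type I interferon response (-1.36, 15 of 20) and MHC class I genes (-0.85, 10 of 12), each at an adjusted p of 0.256 with an estimated correlation. Markers of other cell types moved with these lists: macrophage markers (-2.55, 7 of 8 over the list alone) and endothelial markers (-2.38, 8 of 8), at an adjusted p of 0.256 each with an estimated correlation. Endothelial adhesion genes did too (-2.22, 8 of 8; adjusted p = 0.251 with an estimated correlation). By edgeR 0 of 12208 genes passed over all genes (1641 at an unadjusted p under 0.05, 731 by DESeq2, of which 166 were higher and 565 lower, and 39 without UPS-C). The smallest edgeR adjusted p was 0.0664, shared by the protease CTSC, the vasopressin receptor AVPR1A and the phosphatase PTPRE.

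Collagen and fibroblast genes were higher in immune cells of UPS, in a pattern weighed against 2 explanations. Free RNA stays open: in 15 of the 17 pairs of UPS tumour and immune type, the UMIs of 13 collagen genes not used to estimate it lay between 0.5 and 2 times those expected from the droplets with few UMIs (median ratio 1.08, range 0.533 to 4.73, with 4.73 and 2.94 in the cells named mast cells of UPS 2 and UPS 3, described below), but its share was set on other collagen genes of the same cells, so fibroblasts would give such ratios too. Fibroblasts or doublets named as immune cells may contribute collagen UMIs: in 10 of the 17 pairs the 5% of cells with most of these UMIs held over 3 times their share of all UMIs, which happened in 4 pairs when the UMIs were dealt out by depth alone. In the B cells of UPS 2 these cells held 86.3% of the collagen UMIs and in its dendritic cells 61.9%. Immune cells of LMS showed such concentration too. It was 7.61 times in dendritic cells of LMS 4, 6.61 times in CD4 T cells of LMS 1 and 2.14 times in monocytes and macrophages of LMS 2. The measure therefore cannot tell whether such cells make the difference between the histologies. Expression by the immune cells of UPS themselves was not tested apart from these 2 explanations, so a difference by histology cannot be read from these genes.

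Cells named mast cells had 511 CPM of the mast cell tryptase TPSAB1 in LMS 1, 2.04 in UPS 2 and 0 in UPS 3, and 9.83, 1277 and 1550 CPM of the endothelial gene PECAM1. The B cells of UPS 2 had 4639 CPM of JCHAIN, a plasma cell gene, and 0 of the B cell marker MS4A1. Cancer-associated fibroblasts had 571 to 2528 CPM of the pericyte gene RGS5 except in LMS 4, at 1.45.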
